A study of Arabidopsis thaliana with 4 samples.

How the data were processed

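Expression was measured on 4 Agilent 2-colour arrays of whole Arabidopsis thaliana seedlings (Col-0), 2 for 2 h of salt and 2 for 5 h. Per the labels' protocols, seeds were kept for 3 d at 4 °C in the dark and seedlings were grown at 22 °C with 8 h of light and 16 h of dark on 0.7% agar with 1.5% sucrose. At 14 d they were moved to paper soaked in NaCl solution (300 mM), per the labels' protocols. RNA was extracted with Trizol, and 0.2 µg was labelled with a low-input 2-colour kit, per the labels' protocols. On every array Cy3 carried RNA of untreated seedlings (0 h) and Cy5 carried RNA of salt-treated seedlings, with no dye swap. The series' design text gives 2 biological replicates. The salt samples are numbered and the 0 h sample is not, so 0 h was counted as 1 control sample.

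The deposited array files hold median spot and background intensity in Cy3 and Cy5 as the scanner gave them, with marks for dim, saturated and uneven spots. They also hold intensity after background subtraction and dye normalization by Feature Extraction, per the file headers. A log10 ratio of the processed Cy5 over Cy3 signals is given per spot, per the file headers. The headers name Feature Extraction 11.5.1.1 and the submitters' processing notes name 9.3.2.1. The deposited series table holds log2 ratios, and each of its columns followed that array's log10 ratio on the log2 scale (r from 0.9973 to 0.9998 across probes) with a median shift of its own between 0.0858 and 0.118. Between 83.9% and 87.3% of probes lay within 0.01 of that shift and the rest differed by another amount. The basis of the shift is not stated, and the direction of the ratio was the same.

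The ratios analysed were computed from the scanner intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50 and each array was normalized by loess with control spots at weight 0, without scaling between arrays. Median spot signals were used because the files hold no mean signals, which the planned processing named. Outlier spots, 14 to 19 per array, were left out, and spots of 1 probe were averaged. The 43803 spots that are not controls carried 43603 probes, of which 35595 had a RefSeq transcript as identifier and 34348 matched 1 gene in a table of TAIR10.1 genes. That table was used for names only, since the arrays were annotated on an earlier TAIR10 release. The brightest kept probe stood for a gene. A probe was kept if it was well above background in Cy3 on at least 2 of the 4 arrays or in Cy5 on both arrays of a time, which left 32531 probes and 20412 genes. The log2 ratio of 3 genes was missing on 1 or more arrays. Members of close gene families share sequence, so LTP3 and LTP4, PIP2;2 and PIP2;3, and the LHCB1, JAZ and HAI genes are uncertain as single genes.

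The 2 h and 5 h ratios were each tested against 0, and the 5 h ratios against the 2 h ratios, with limma's moderated test (2 residual degrees of freedom, prior degrees of freedom 5.43) and Benjamini-Hochberg adjustment at 0.05. A ratio tested against 0 leaves out the control's own spread, and a gene's dye bias cannot be told apart from the salt effect. Such a bias drops out of 5 h against 2 h, as does the control if 1 sample was shared. Errors are limma's moderated SE of a log2 change, with 2 arrays per time. That SE pools the spread of both times and is drawn toward a value common to all genes. It is therefore not the spread of 1 time's 2 arrays. In 20 simulations without any effect but with 1 shared control, the same test called 1130 genes on average at 2 h and 1170 at 5 h, 3.15 genes in 5 h against 2 h, and 0.6 changes of at least 2-fold. The simulated control deviated with each gene's residual SD between arrays. The true spread of the 0 h sample was not measured, so these counts hold for that setting only. They do not show that 2-fold changes are free of control variation. Sizes of at least 2-fold were therefore counted beside all calls. Tested on simulated data of 20409 genes with 50 changed genes of each size, a log2 change of 0.25 was recovered in 92% of genes for 2 h, 96% for 5 h and 68% for 5 h against 2 h. A log2 change of 1 was recovered in 100% in each comparison. These simulated data held no shared control deviation and few changed genes, so the rates hold for that setting only.

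Gene lists were tested with camera (preset correlation 0.01), adjusted over the 75 tests of 25 lists in 3 comparisons. Camera with an estimated correlation, which has only 2 degrees of freedom here, and fry were run beside it. On simulated data camera called the shifted list and 0 of 20 unshifted lists in each comparison. The simulated noise was independent between genes and few genes changed, so correlated members and widespread change were not tested. The 26 lists covered dehydration protection, abscisic acid synthesis and breakdown, abscisic acid receptors, clade A phosphatases, stress transcription factors, senescence, ion transport and osmolytes. They also covered reactive oxygen, heat shock, jasmonate, ethylene, salicylic acid, photosynthesis, morning and evening clock genes, cell wall, auxin and aquaporins. Others held glucosinolates, flavonoids, seed storage, root-preferential genes, guard cells and reference genes. The list of cytosolic ribosomal proteins had no test, because no column of gene descriptions was used. Lists, tests, thresholds, alternatives and the rule for named genes were fixed before the data were examined. That rule took the 6 largest rises and falls per comparison that moved the same way on both arrays, up to 4 called members of each list with the largest change, and all clock and reference genes. Where one side of a ratio was not well above background, a bound was computed per channel after loess and scaling of intensities between arrays (Aquantile). It divides the bright group's mean by the dim group's mean, with each dim signal set to at least the lowest well-above-background signal, and it stays open to dye bias. Where the fitted ratio was smaller than this bound, the ratio was taken as the bound.

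All 4 arrays came from 1 slide and 1 scan batch, so batch was not tested. The 2 h arrays lay at positions 1 and 2 of the slide and the 5 h arrays at positions 3 and 4. Position therefore cannot be told apart from time. The alternatives were the Feature Extraction ratio, no background subtraction, median centring, Aquantile, no filter or a strict filter on dim probes, saturated probes left out, the mean of a gene's probes, an intensity trend with a robust prior, a 2-fold size threshold, the replicate number as a block, the deposited log2 table, and each array left out in turn. The groups of 2 arrays are too small for a test of single arrays standing apart or of other splits of the samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.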

Results

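Whole 14-day-old seedlings exposed to 300 mM NaCl for 2 h (2 arrays) or 5 h (2 arrays) were each compared on the same array with untreated seedlings, written 0 h. Median spot signals ranged from 252 to 282 in Cy3 (0 h) and from 342 to 372 in Cy5 (salt), over backgrounds of 33 to 37.5 and 52.5 to 54. On each array between 70.5% and 72.4% of 43803 spots lay well above background in a channel, and 0 spots were saturated. Across genes, which are not independent replicates, log2 ratios correlated at r = 0.9897 between the 2 h arrays, 0.9954 between the 5 h arrays and 0.8026 to 0.8049 between arrays of different times. The spread of the difference between arrays was 0.0953 and 0.0733 (SD from the median absolute deviation, log2) within a time and 0.435 to 0.444 across times. With 2 arrays per time, their number limits the precision. Every log2 change is the mean of 2 arrays per time ± limma's moderated SE, which is pooled over both times. Each called gene named below passed limma's test with an adjusted p between 5e-11 and 0.0413.

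The first comparison asked how the seedlings' transcripts differed after 2 h of salt. No seedlings moved to paper without NaCl were analysed. In all 3 comparisons an effect of salt therefore cannot be told apart from one of the transfer or, unless sampling was matched, of time of day. Jasmonate genes and stress transcription factors rose together and held several of the largest rises, while transcripts of seed storage proteins fell furthest. CYP94B3, which oxidises the active jasmonate, rose by 7.32 ± 0.039 on the log2 scale (160-fold). WRKY18 and WRKY40, regulators of defence and abscisic acid responses, rose by 6.11 ± 0.043 and 5.84 ± 0.037. RAP2.6 and RRTF1, ERF-family transcription factors, rose by 6.05 ± 0.036 and 5.97 ± 0.062, and AT2G38240, a gene of the jasmonate-induced oxygenases, by 6.75 ± 0.038.

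All 26 measured jasmonate genes rose at 2 h, 24 of them at least 2-fold (median log2 change 3.62, camera adjusted p = 3.3e-12). They included the synthesis gene LOX3 (5.64 ± 0.043) and the repressor genes JAZ10 (5.17 ± 0.034) and JAZ5 (4.61 ± 0.053). Of 34 stress transcription factors 33 rose and 1 fell (median 3.15, adjusted p = 1.57e-12), among them the DREB-type factor DDF1 (5.44 ± 0.037) and the zinc finger gene ZAT10 (4.79 ± 0.036). In camera with an estimated correlation, which has 2 degrees of freedom here, neither call held (adjusted p = 0.198 with an estimated correlation for each). The estimate was −0.0386 for jasmonate genes, below the preset 0.01, and 0.0415 for the transcription factors.

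Ethylene genes rose in 13 of 13 cases (median 1.05, adjusted p = 5.64e-05), led by ACS6 and ACS2, which make the ethylene precursor (3.51 ± 0.037 and 3.00 ± 0.037), and by the response factor ERF1 (3.36 ± 0.037). Salicylic acid and pathogen genes rose in 15 of 17 cases and fell in 1 (median 1.1, adjusted p = 5.64e-05), with PR2, a glucanase, at 3.00 ± 0.036 and the regulator CBP60G at 2.48 ± 0.038. Senescence genes rose in 20 of 25 cases and fell in 4 (median 1.51, adjusted p = 0.000273), and the NAC factors NAC055 (4.74 ± 0.038), NAC019 (4.01 ± 0.034) and RD26 (3.85 ± 0.046) led them. For each of these lists the adjusted p = 0.198 with an estimated correlation.

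Dehydration protection genes rose in 16 of 24 cases and fell in 6 (median 1.25, adjusted p = 0.0115, and adjusted p = 0.243 with an estimated correlation). RD20, a caleosin, rose by 4.17 ± 0.034 and the dehydrin genes ERD10 and COR47 by 3.39 ± 0.038 and 2.93 ± 0.05. Clade A phosphatases, which restrain abscisic acid signalling, rose in 7 of 9 cases and fell in 2 (median 1.81, adjusted p = 0.0183, and adjusted p = 0.229 with an estimated correlation), with HAI1 at 2.52 ± 0.05. Proline, raffinose and polyamine genes rose in 13 of 18 cases and fell in 3 (median 0.562, adjusted p = 0.00575, and adjusted p = 0.198 with an estimated correlation), led by the galactinol synthase gene GOLS3 (2.77 ± 0.042) and the raffinose synthase gene RS5 (2.59 ± 0.036). Aquaporins, the water channels, rose in 14 of 18 cases and fell in 3 (median 1.05, adjusted p = 0.00217, and adjusted p = 0.198 with an estimated correlation), with PIP2;3 at 3.97 ± 0.034. Reactive oxygen genes rose in 16 of 25 cases and fell in 7 (median 0.447, adjusted p = 0.0161, and adjusted p = 0.243 with an estimated correlation). Among them the glutathione transferase GSTU4 rose by 2.96 ± 0.035 and the superoxide dismutase CSD2 fell by 2.23 ± 0.034. Auxin genes rose in 10 of 14 cases and fell in 3 (median 0.659, adjusted p = 0.024, and adjusted p = 0.232 with an estimated correlation), with the auxin-conjugating enzyme gene GH3.3 at 4.67 ± 0.034.

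Seed storage and maturation genes fell in 11 of 13 cases and rose in 2 (median −1.45, adjusted p = 0.000981, and adjusted p = 0.198 with an estimated correlation). CRU3 and CRA1, seed storage globulins, stood at −6.54 ± 0.077 and −6.10 ± 0.048, CRU3 lying well above background after salt on 1 of the 2 arrays. The seed peroxiredoxin PER1 was at least 19.4-fold lower, the oleosin OLEO2 at least 8.61-fold and the loci AT5G35660 and AT2G28490 at least 29.7-fold and 9.87-fold. BGLU19, a beta-glucosidase, fell by 4.12 ± 0.048. Under the scalings tried the list's median ranged from −3.4 to −1.41. Keeping only probes well above background in both channels on all 4 arrays left 4 members (median −0.37, adjusted p = 0.747, range over the alternatives 3e-05 to 0.747), and since it removes members that fell to background it does not test the fall.

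The other lists did not pass as lists at 2 h. Abscisic acid synthesis and breakdown genes rose in 8 of 11 cases and fell in 3 (adjusted p = 0.152). NCED3, which catalyses the committed step of synthesis, stood at 3.27 ± 0.053. Abscisic acid receptors rose in 6 of 9 cases and fell in 2 (adjusted p = 0.12), with PYL7 at 3.17 ± 0.038. Heat shock genes rose in 10 of 18 cases and fell in 5 (adjusted p = 0.152), with the factor gene HSFA6B at 5.61 ± 0.04. Ion transport genes rose in 8 of 22 cases and fell in 9 (adjusted p = 0.683), and their median of 0.00789 and mean of −0.0191 differed in sign. Photosynthesis genes rose in 16 of 34 cases and fell in 12 (adjusted p = 0.907), with a median of 0.0684 and a mean of −0.0287, and PORA, a protochlorophyllide reductase, fell by 0.93 ± 0.04. Cell wall genes rose in 11 of 19 cases and fell in 8 (adjusted p = 0.635), with the expansin EXPA8 at −2.33 ± 0.037. Glucosinolate genes rose in 10 of 17 cases and fell in 3 (adjusted p = 0.0819), and flavonoid genes rose in 7 of 13 and fell in 4 (adjusted p = 0.545). Relative to all genes, the medians of the ion transport (0.00782 to 0.054), photosynthesis (0.0684 to 0.367) and flavonoid lists (0.03 to 0.142) stayed above 0 under every scaling tried, and they fell below 0 only with the Feature Extraction ratio, together with the median of all genes.

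Among markers of tissues, root-preferential genes fell in 10 of 16 cases and rose in 5 (median −0.363, adjusted p = 0.152), with the iron transporter IRT1 at 2.04 ± 0.037. Guard cell genes rose in 4 of 6 cases and fell in 1 (adjusted p = 0.346). Clock genes that peak around dawn rose in 7 of 13 cases and fell in 5 (adjusted p = 0.456), and evening genes rose in 6 of 10 and fell in 3 (adjusted p = 0.104). CCA1, a core morning clock gene, fell by 0.30 ± 0.036 and LHY did not pass (−0.03 ± 0.036), while the evening gene LUX rose by 2.02 ± 0.036. One of the 3 CCA1 probes and 1 of the 2 LNK2 probes went the other way. Of 7 reference genes 5 rose and 2 did not pass (median 0.283, adjusted p = 0.0532). UBQ10, a polyubiquitin gene, rose by 2.19 ± 0.034, and TIP41L (0.05 ± 0.045) and UBC21 (−0.01 ± 0.044) did not pass.

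At 2 h 8447 genes were higher and 8256 lower among 20410 tested, with a median size of 0.399 for called log2 changes. A gene's direction is that of its brightest probe. Among 6084 genes with several kept probes, 1241 had probes of opposite sign at 2 h, counted at any size. In 0 of them did probes go opposite ways by at least 2-fold each. With the Feature Extraction ratio, which moved the median of all genes by −0.145, 6563 were higher and 10355 lower (38.8% of called genes higher in place of 50.6%), and with median centring 8990 and 6949 (56.4%). At least 2-fold, 1990 were higher and 476 lower, and at least 8-fold, 227 and 11. By the Feature Extraction ratio the 2-fold counts were 2439 and 1550 (61.1% higher in place of 80.7%), and 2737 and 1210 by the deposited log2 values (69.3%). Adjusted over the list alone, 24 of the 25 lists had the same number of called members as over all genes, and reactive oxygen had 24 in place of 23.

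**Figure D1:**
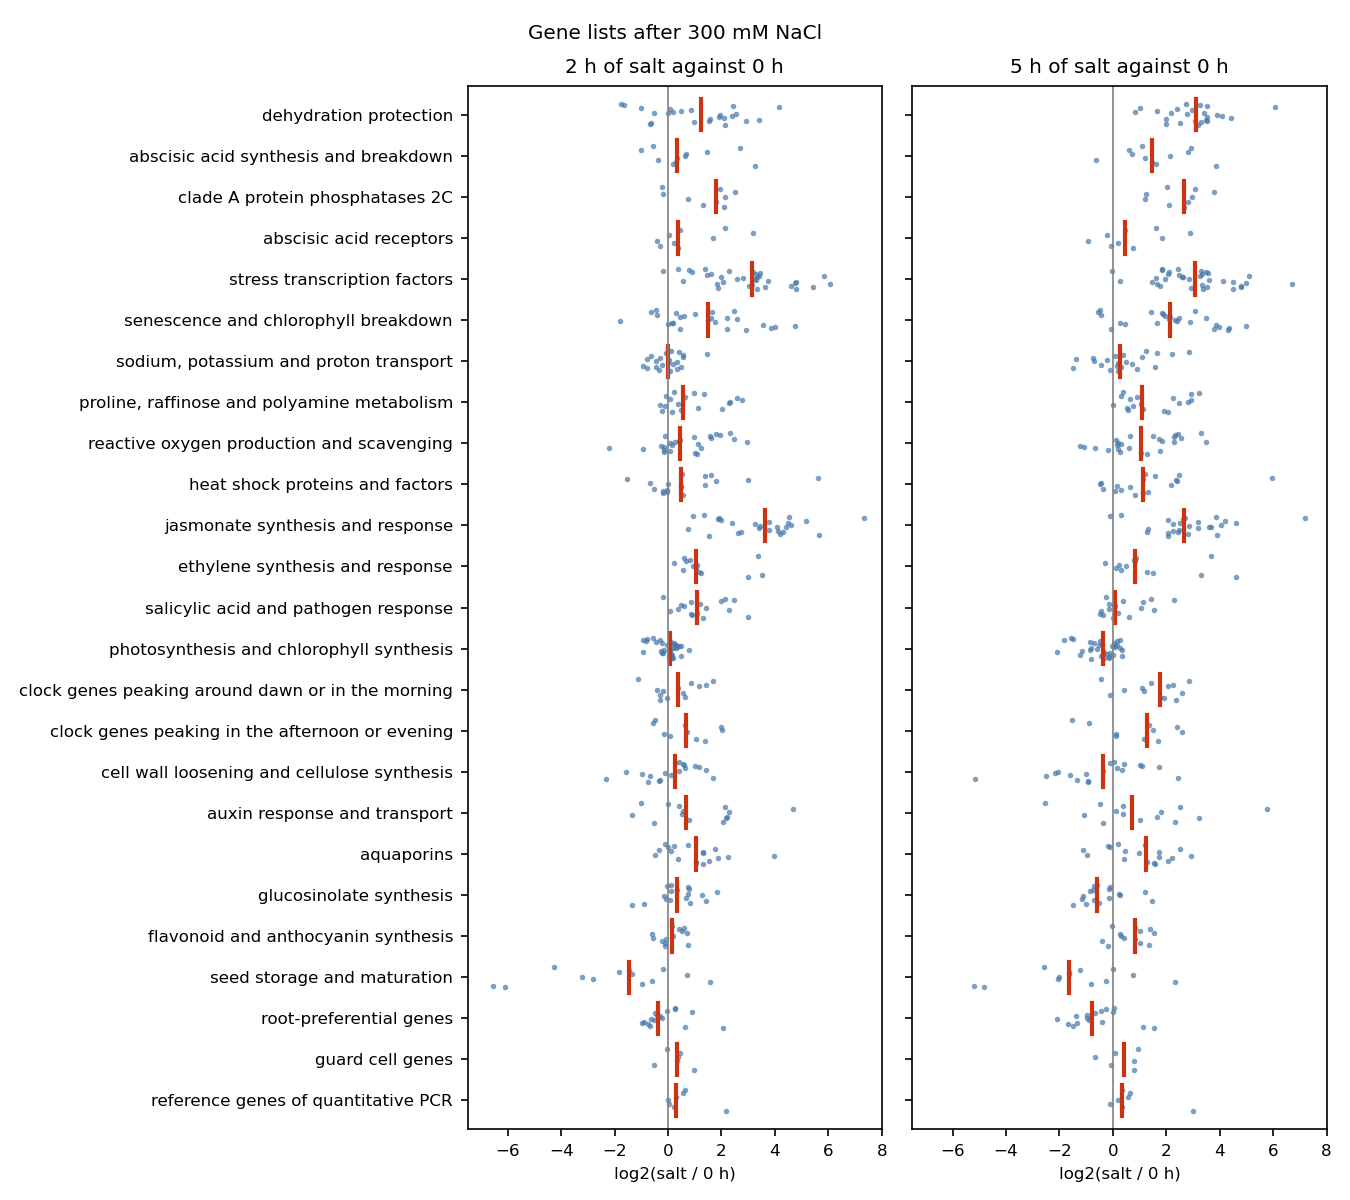
Each point is 1 gene of a list fixed beforehand, placed at its mean log2 ratio of salt over 0 h on 2 arrays, at 2 h (left) and 5 h (right), and red bars mark list medians. Jasmonate genes sit highest at 2 h (median 3.62), dehydration genes at 5 h (3.12), and seed storage genes lie lowest at both times (−1.45 and −1.63).

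The second comparison asked the same of 5 h of salt. Dehydration protection genes now rose without exception, the lists of abscisic acid metabolism, clade A phosphatases and senescence stood higher, and the expansin EXPA8 and photosynthesis genes were among those that fell. RD20 rose by 6.06 ± 0.034 (66.6-fold), RAP2.6 by 6.70 ± 0.036, CYP94B3 by 7.17 ± 0.039 and AT2G38240 by 6.94 ± 0.038. ELI3-2, a defence-induced alcohol dehydrogenase, rose by 6.15 ± 0.04 and the glycosyltransferase UGT76E12 rose 63.9-fold. EXPA8, a cell wall expansin, fell by 5.17 ± 0.037 (36-fold), and the defence-linked gene PCC1 fell by 4.08 ± 0.068.

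All 24 dehydration protection genes rose at 5 h, 22 at least 2-fold (median 3.12, camera adjusted p = 4.05e-09), among them KIN1 (4.40 ± 0.035), the dehydrin LTI30 (4.09 ± 0.037) and LEA4-5 (3.88 ± 0.036). Abscisic acid synthesis and breakdown genes rose in 10 of 11 cases and fell in 1 (median 1.47, adjusted p = 0.00195), with NCED3 at 3.85 ± 0.053 and the breakdown gene CYP707A1 at 2.82 ± 0.034. All 9 clade A phosphatases rose (median 2.65, adjusted p = 0.000278), with HAI1 at 3.79 ± 0.05 and HAB1 at 2.80 ± 0.034. Senescence genes rose in 21 of 25 cases and fell in 3 (median 2.12, adjusted p = 2.86e-05), including ORE1, a promoter of leaf ageing, at 4.32 ± 0.035. For each of these lists the adjusted p = 0.198 with an estimated correlation.

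Stress transcription factors rose in 33 of 34 cases (median 3.08, adjusted p = 2.04e-11), with ZAT6 at 5.00 ± 0.034 and DREB2A, a factor of drought responses, at 4.79 ± 0.038. Jasmonate genes rose in 25 of 26 cases (median 2.66, adjusted p = 4.05e-09), with JAZ7 at 4.61 ± 0.035. Ethylene genes rose in 12 of 13 cases and fell in 1 (median 0.819, adjusted p = 0.00327), with ACS2 at 4.61 ± 0.037. Proline, raffinose and polyamine genes rose in 17 of 18 cases (median 1.09, adjusted p = 3.19e-05), with the aldehyde dehydrogenase ALDH7B4 at 3.21 ± 0.035 and ADC2, which begins polyamine synthesis, at 2.92 ± 0.042. Reactive oxygen genes rose in 21 of 25 cases and fell in 4 (median 1.06, adjusted p = 0.00155), with the kinase gene OXI1 9.87-fold higher. Heat shock genes rose in 14 of 18 cases and fell in 3 (median 1.12, adjusted p = 0.0031). The list's largest rises were transcription factor genes, HSFA6B (5.94 ± 0.04) and HSFB2A (2.47 ± 0.045). Aquaporins rose in 14 of 18 cases and fell in 4 (median 1.22, adjusted p = 0.00623), with TIP1;1 at 2.50 ± 0.037. Camera with the correlation estimated, which has 2 degrees of freedom, called none of these lists (adjusted p = 0.198 with an estimated correlation for each list).

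Flavonoid genes rose in 10 of 13 cases and fell in 1 (median 0.818, adjusted p = 0.0274, and adjusted p = 0.301 with an estimated correlation), with the anthocyanin regulator PAP1 at 1.53 ± 0.034 and PAP2 at least 2.02-fold higher. Keeping only bright probes, with 12 members left, ended that call (median 0.611, adjusted p = 0.0515, range over the alternatives 0.0164 to 0.0515). Photosynthesis genes fell in 23 of 34 cases and rose in 6 (median −0.351, adjusted p = 0.00575, and adjusted p = 0.198 with an estimated correlation), with the antenna protein gene LHCB2.3 at −2.08 ± 0.038 and PORA at −1.82 ± 0.04. Glucosinolate genes fell in 12 of 17 cases and rose in 4 (median −0.607, adjusted p = 0.0415, and adjusted p = 0.361 with an estimated correlation). Among them MYB28, a regulator of the aliphatic branch, fell by 1.48 ± 0.038 and MYB51, of the indolic branch, rose by 1.48 ± 0.043. The glucosinolate call ended with the Feature Extraction ratio (adjusted p = 0.0565, range 0.0235 to 0.0565), where the median was further from 0 (−0.815).

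Seed storage and maturation genes fell in 10 of 13 cases and rose in 2 (median −1.63, adjusted p = 0.00977, and adjusted p = 0.243 with an estimated correlation). CRU3 stood at −5.20 ± 0.077, CRA1 at −4.84 ± 0.048 and PER1 at −2.59 ± 0.034, while ABI5, a transcription factor of abscisic acid responses, rose by 2.32 ± 0.036. AT5G35660 stood at −3.92 ± 0.034 and BGLU19 at −3.91 ± 0.048. The list's call ended with the Feature Extraction ratio (adjusted p = 0.12, range over the alternatives 0.00193 to 0.855), where the median fall was larger (−2.73). With bright probes only, 4 members were left (median −0.23, adjusted p = 0.855), which does not test the fall for the reason given at 2 h. With dim members set at their bounds, the list's medians were −1.45 at 2 h and −1.62 at 5 h.

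Root-preferential genes fell in 12 of 16 cases and rose in 2 (median −0.784, adjusted p = 0.0115, and adjusted p = 0.223 with an estimated correlation). The Casparian strip gene CASP1 fell by 2.08 ± 0.043, the root hair gene COBL9 fell by 1.50 ± 0.064 and the root hair expansin EXPA7 was at least 3.23-fold lower. Guard cell genes rose in 3 of 6 cases and fell in 1 (adjusted p = 0.379). The fall of root markers was seen in the same samples as the changes of the dehydration and photosynthesis genes.

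Clock genes that peak around dawn rose in 11 of 13 cases and fell in 2 at 5 h (median 1.77, adjusted p = 0.00195, and adjusted p = 0.198 with an estimated correlation). CCA1 rose by 2.35 ± 0.036, LHY by 1.91 ± 0.036, RVE1 by 2.58 ± 0.036 and COL1 by 2.85 ± 0.045, and PRR7 fell by 0.09 ± 0.036. Evening clock genes rose in 8 of 10 cases and fell in 2 (median 1.26, adjusted p = 0.0635), with ELF4 6.04-fold higher, TOC1 at 1.17 ± 0.034 and CHE at −1.53 ± 0.034. GI and ELF3 rose by 0.10 ± 0.037 and 0.12 ± 0.044. With the Feature Extraction ratio, whose median of all genes lay at −0.135, they stood at −0.105 and −0.054, which is 0.03 and 0.081 relative to all genes. The hour of collection was not given in the sources used, and 0 h, 2 h and 5 h of salt differ in time of day unless sampling was matched.

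**Figure D2:**
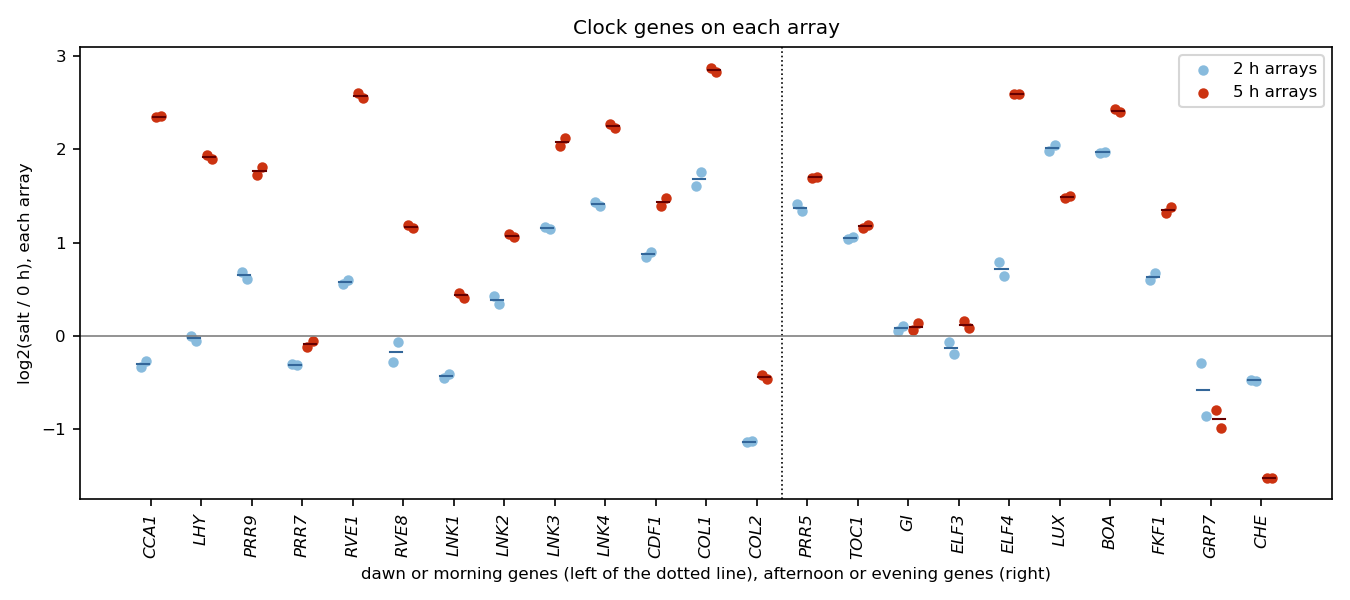
Each point is the log2 ratio of salt over 0 h of a clock gene on 1 array, with bars at the mean of the 2 arrays of a time, for dawn genes (left) and evening genes (right). At 5 h CCA1 (2.35) and LHY (1.91) lie well above their 2 h values of −0.30 and −0.03.

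The remaining lists did not pass at 5 h. Salicylic acid genes rose in 8 of 17 cases and fell in 6 (median 0.0861, adjusted p = 0.379), with CBP60G 4.92-fold higher. Ion transport genes rose in 14 of 22 cases and fell in 7 (median 0.253, adjusted p = 0.177), with the vacuolar antiporter genes CAX3 at 2.84 ± 0.036 and NHX1 at 1.56 ± 0.039. Abscisic acid receptors rose in 6 of 9 cases and fell in 2 (adjusted p = 0.214), with PYL7 at 2.90 ± 0.038 and PYL4 at −0.92 ± 0.039. Cell wall genes fell in 11 of 19 cases and rose in 7 (median −0.381, adjusted p = 0.219), with EXPA11 at −2.51 ± 0.035 and EXPA10 at 2.45 ± 0.043. Auxin genes rose in 10 of 14 cases and fell in 4 (adjusted p = 0.0936), with GH3.3 at 5.78 ± 0.034 and the auxin exporter PIN7 at −2.55 ± 0.041. Of 7 reference genes 6 rose (median 0.33, adjusted p = 0.0613) and TIP41L did not pass (−0.09 ± 0.045), and UBQ10 rose by 3.01 ± 0.034. UBC21 rose by 0.19 ± 0.044, which became −0.071 with the Feature Extraction ratio, or 0.064 relative to all genes, and GAPC2 rose by 0.33 ± 0.043, turning to −0.08 with the mean of its probes.

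At 5 h 8994 genes were higher and 8912 lower among 20412, with a median size of 0.549. Of the 6084 genes with several kept probes, 860 had probes of opposite sign at 5 h, and 1 had probes opposite by at least 2-fold each. At least 2-fold, 2773 were higher and 1487 lower, and at least 8-fold, 314 and 22. The Feature Extraction ratio gave 7623 higher and 10214 lower (42.7% of called genes higher in place of 50.2%), and 3170 and 3129 at least 2-fold (50.3% in place of 65.1%). Adjusted over the list alone, 25 of the 25 lists had the same number of called members as over all genes.

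**Figure D3:**
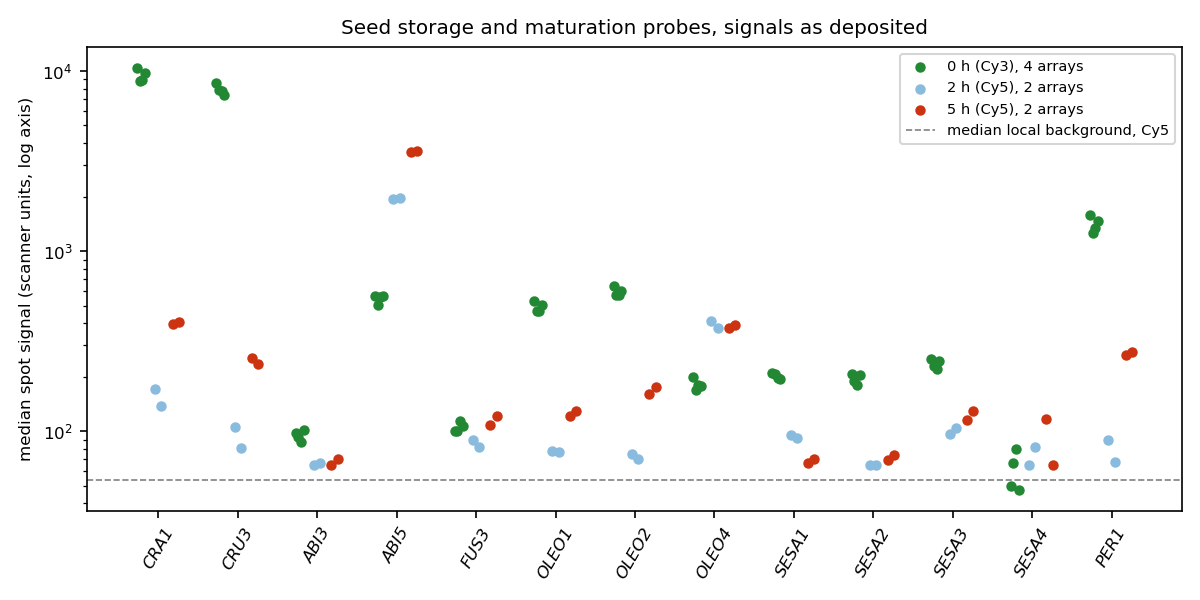
Median spot signals of the seed storage and maturation probes as deposited, on a log axis, for 0 h (4 arrays), 2 h and 5 h (2 arrays each), with a dashed line at the local Cy5 background of 53.75. CRA1 read 8859 to 10401 at 0 h, 138 to 173 at 2 h and 394 to 403 at 5 h.

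The third comparison asked what differed between 5 h and 2 h, where a fixed dye bias drops out, as does the control if it was shared. Position on the slide went with time and does not drop out. Genes of dehydration protection and abscisic acid metabolism, and the morning clock, stood higher at 5 h, while jasmonate, salicylic acid, glucosinolate and photosynthesis genes stood lower. The lipid transfer proteins LTP3 and LTP4 were higher by 4.94 ± 0.048 and 4.49 ± 0.059, and SAG29, a sugar transporter of senescing leaves, by 4.19 ± 0.051. The loci AT3G59930 and AT3G17520 were higher by 3.96 ± 0.05 and 3.92 ± 0.063, and the glyoxalase GLYI7 by 3.88 ± 0.051. CYP82G1 and TPS04, which make a volatile terpene, differed by −3.93 ± 0.065 and −2.97 ± 0.093, the desaturase ADS1 by −3.64 ± 0.058 and PCC1 by −3.42 ± 0.096. AT5G03350 and AT2G41090 differed by −3.44 ± 0.061 and −3.17 ± 0.056.

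Dehydration protection genes were higher at 5 h in 23 of 24 cases (median 1.91, camera adjusted p = 2.04e-11), with LEA7 at 3.38 ± 0.056 and RAB18, a dehydrin, at 3.16 ± 0.054. Abscisic acid synthesis and breakdown genes were higher in 9 of 11 cases and lower in 1 (median 1.18, adjusted p = 0.000618), with AAO3, the last synthesis step, at 1.50 ± 0.056. All 9 clade A phosphatases were higher (median 0.99, adjusted p = 9.75e-05), with HAI3 at 2.26 ± 0.048 and AHG1 at least 2.53-fold higher. Senescence genes were higher in 17 of 25 cases and lower in 3 (median 0.6, adjusted p = 0.000117), with the chlorophyll breakdown genes SGR2 at 1.66 ± 0.061 and PAO at 1.56 ± 0.054. Proline, raffinose and polyamine genes were higher in 12 of 18 cases and lower in 3 (median 0.352, adjusted p = 0.00382), with the proline synthesis genes P5CS2 and P5CS1 at 2.12 ± 0.058 and 1.89 ± 0.053. Heat shock genes were higher in 14 of 18 cases and lower in 3 (median 0.309, adjusted p = 0.00359), with HSP90.1 at 1.36 ± 0.054. All 13 dawn clock genes were higher (median 0.925, adjusted p = 1.39e-06), with CCA1 at 2.65 ± 0.05. For each of these lists the adjusted p = 0.198 with an estimated correlation.

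Ion transport genes were higher in 13 of 22 cases and lower in 7 (median 0.38, adjusted p = 0.0212, and adjusted p = 0.223 with an estimated correlation), with CAX3 at 2.41 ± 0.051 and NHX2, a vacuolar antiporter, at 1.08 ± 0.055. Flavonoid genes were higher in 9 of 13 cases and lower in 2 (median 0.602, adjusted p = 0.00696, and adjusted p = 0.249 with an estimated correlation), with F3H at 1.16 ± 0.057. Reactive oxygen genes were higher in 14 of 25 cases and lower in 6 (median 0.395, adjusted p = 0.0212, and adjusted p = 0.249 with an estimated correlation), with the catalase CAT2 at 1.69 ± 0.052. That call ended with the Feature Extraction ratio (median 0.222, adjusted p = 0.0574) and with median centring (median 0.302, adjusted p = 0.07), in a range from 0.0129 to 0.07. Seed storage and maturation genes were higher at 5 h than at 2 h in 10 of 13 cases and lower in 1 (median 0.354, adjusted p = 0.00327, and adjusted p = 0.222 with an estimated correlation). CRA1 differed by 1.26 ± 0.068, and PER1 was at least 3.23-fold and OLEO2 at least 2.14-fold higher. With bright probes only, 4 members were left and the call ended (median 0.482, adjusted p = 0.0702, range 0.0016 to 0.0702). With dim members at their bounds the median over all 13 was 0.354 as well. ABI3 and SESA2, below background in Cy5 at both times, had no bound, so this equal median does not show stability. SESA2 (0.173 ± 0.052) was still counted among the 10 higher. So was SESA4 (0.194 ± 0.071), well above background in Cy5 on 1 of the 2 arrays at each time. SESA1, the 1 lower, was not well above background at 5 h.

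Salicylic acid and pathogen genes were lower at 5 h in 15 of 17 cases and higher in 1 (median −0.684, adjusted p = 8.42e-05), with PR2 at −2.41 ± 0.051 and PAD3, a camalexin synthesis gene, at −1.62 ± 0.056. Jasmonate genes were lower in 19 of 26 cases and higher in 4 (median −0.601, adjusted p = 0.00327), with the synthesis genes AOC1 at −1.86 ± 0.048 and OPR3 at −1.84 ± 0.053. Glucosinolate genes were lower in 15 of 17 cases and higher in 0 (median −0.798, adjusted p = 3.68e-05), with MYB34 at −1.35 ± 0.048. Photosynthesis genes were lower in 29 of 34 cases and higher in 2 (median −0.427, adjusted p = 8.42e-05), with LHCB1.4 at −1.27 ± 0.052. Cell wall genes were lower in 14 of 19 cases and higher in 3 (median −0.469, adjusted p = 0.00856), with EXPA8 at −2.84 ± 0.053 and XTH7, a wall-remodelling enzyme, at −2.05 ± 0.048. Root-preferential genes were lower in 13 of 16 cases and higher in 2 (median −0.502, adjusted p = 0.00327), with CASP1 at −1.44 ± 0.061 and EXPA7 at least 1.91-fold lower. For each of these lists the adjusted p = 0.198 with an estimated correlation.

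Stress transcription factors did not differ as a list (17 of 34 higher, 13 lower, adjusted p = 0.248), with ABF4 at 1.44 ± 0.059 and DDF2 at −1.28 ± 0.053. Evening clock genes were higher in 6 of 10 cases and lower in 2 (adjusted p = 0.258), with ELF4 at 1.88 ± 0.062. Ethylene genes were higher in 4 of 13 cases and lower in 6 (adjusted p = 0.703), with ACS2 at 1.62 ± 0.053. Auxin genes were higher in 7 of 14 cases and lower in 5 (adjusted p = 0.703), their median of 0.0859 and mean of −0.00685 differing in sign. Aquaporins were higher in 10 of 18 cases and lower in 6 (adjusted p = 0.379), abscisic acid receptors higher in 2 of 9 and lower in 4 (adjusted p = 0.662). Relative to all genes, the medians of the receptor (−0.0369 to 0.0478) and ethylene lists (−0.107 to 6e-04) had both signs over the scalings tried. Guard cell genes were higher in 3 of 6 cases and lower in 3 (adjusted p = 0.703), with MYB60 at −1.02 ± 0.079 and OST1, a kinase of stomatal closure, at 0.98 ± 0.05. Of 7 reference genes 3 were higher and 1 lower (adjusted p = 0.348). EF1A did not pass (0.06 ± 0.049), but it fell by the mean of its probes (−0.30) and with median centring (−0.34).

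In 5 h against 2 h 6853 genes were higher and 7941 lower among 20410, with a median size of 0.408. At least 2-fold, 884 were higher and 701 lower, and at least 8-fold, 14 and 5. The deposited log2 table gave 1158 and 1432 at least 2-fold (44.7% higher in place of 55.8%). Adjusted over the list alone, 23 of the 25 lists had the same number of called members as over all genes, while proline, raffinose and polyamine genes had 16 in place of 15 and aquaporins 17 in place of 16. Over the 3 comparisons 46 of 75 list tests passed, and 0 of them held with an estimated correlation, for which the smallest adjusted p was 0.198. With its 2 degrees of freedom that version of camera called no list. The losses therefore do not tell whether correlated members made a call. Fry, which asks only whether a list's genes move on balance one way, passed for 24, 25 and 23 of the 25 lists at 2 h, at 5 h and between them.

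The last comparison set the responses at both times side by side. Genes that rose at both times included CYP94B3, RAP2.6, NAC055 and NCED3, and those that fell at both included CRA1, CRU3 and EXPA8. At least 2-fold, 1573 genes were higher at both times and 317 lower at both among 20410 genes (270.2 and 34.68 for independent lists of these sizes), and 13 went opposite ways. Of any size, 6633 were higher at both (3721 if independent) and 6345 lower at both (3605), and 2039 went opposite ways. The 0 h sample was counted as 1 control of both ratios, and a shared control raises such overlaps: simulations with no effect and 1 shared control gave 199 genes higher and 202 lower at both times. Across genes the log2 changes at 2 h and 5 h correlated at r = 0.8067 with a covariance of 0.6064. The simulations gave 0.666 and 0.00369. All these simulated values rest on a control deviation set to each gene's residual SD between arrays. The simulated correlation follows from that setting, and the control's spread was not measured, so the 2 correlations cannot be weighed against each other. By the Feature Extraction ratio 1098 genes were at least 2-fold lower at both times, and 878 by the deposited values.

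**Figure D4:**
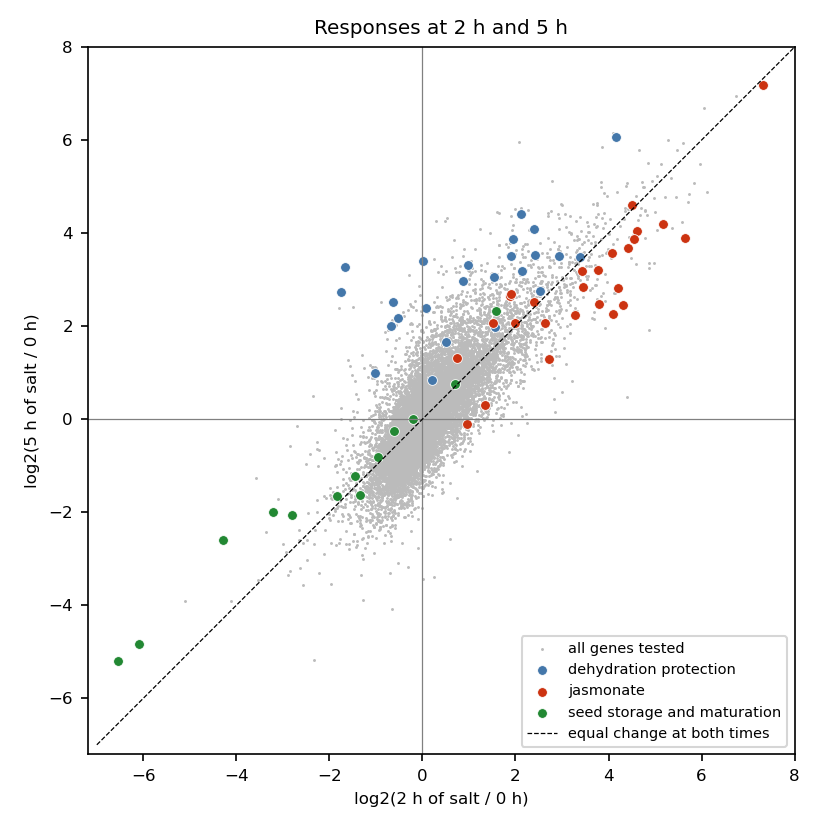
Each point is a gene at its mean log2 ratio of salt over 0 h at 2 h (horizontal) and 5 h (vertical), 2 arrays each, with 3 lists in colour and a dashed line of equal change. Jasmonate genes lie mostly below the line, dehydration genes above it, and most seed storage genes in the lower left.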

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

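All tests of explanations in this part were chosen only after the results were seen.

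Transcripts of seed storage proteins stood far lower after salt: CRA1 read 8859 to 10401 in the 0 h channel against 138 to 173 at 2 h, and CRU3 read 7337 to 8558 against 81 to 106. A dye bias fixed for each gene is argued against as the whole cause, though not as a part of it, because it would cancel between the times. Of 10 list members lower at both times, 8 were above background at either time, 3 of them at both, and their median 5 h minus 2 h log2 change was 0.916 with dim members at their bounds, CRA1 standing 1.265 ± 0.068 higher at 5 h. Seed or embryo RNA in the 0 h sample, for example from seeds that had not germinated, may account for the pattern: 8 of 10 storage protein, oleosin and peroxiredoxin members were lower at both times and 1 was higher, with ABI5, which responds to abscisic acid beyond seeds and rose at both times, outside those 10. This stays open and cannot be told apart from an effect of salt on these genes, since the unnumbered 0 h sample counts as 1 control and was set against salt on every array.

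Clock genes stood higher at 5 h, with dawn genes such as CCA1 and LHY rising between 2 h and 5 h. A fixed dye bias alone is argued against for the dawn list by its median 5 h minus 2 h log2 change of 0.925. The evening median (0.189, camera adjusted p = 0.258) decides nothing, as 6 of 10 members were higher at 5 h than at 2 h and 2 lower. A fixed bias forbids such differences, so it is argued against as the whole cause for these 8 members and stays open for the 2 not called. Over the scalings tried the dawn median at 5 h ranged from 1.77 to 2, so the choice among them did not make it. Relative to all genes it stayed at 1.75 or more, but that measure cancels any shift of a whole array and cannot test one. Time of day alone could move these genes, and it was taken to predict opposite directions for the 2 lists. That prediction depends on the hour of 0 h and on how close together the peaks within a list lie, neither of which was tested. The dawn median at 5 h was 1.77 (95% interval of the median from the order of its members 0.432 to 2.35) and the evening median 1.26 (−0.896 to 2.42), so the evening list leaves time of day open. These intervals treat the members of a list as independent. Time of day cannot be told apart from salt here, since no untreated seedlings at 2 h or 5 h were analysed and the hour of collection is not given in the sources used, and an effect of salt on the clock was not tested.

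Arrays of 1 time were nearly alike, with a median residual SD of 0.0491 on the log2 scale, and most genes were called in each comparison. Spot noise alone is argued against, because replicate differences of separate probes of a gene correlated at r = 0.221 for the 2 h pair (5601 pairs of probes) and 0.0704 for the 5 h pair (5600 pairs), each with a permutation p of 1e-04, the smallest that 10000 permutations can give. The SD of this replicate difference that separate probes shared was 0.0491 at 2 h and 0.0208 at 5 h. It belongs to a difference of 2 arrays, so it cannot be set directly beside the residual SD of single arrays. One RNA extract on both arrays of a time could give so small a spread, and it cannot be told apart from separate samples that vary little, because the error of labelling and hybridisation was not measured here. The series' design text gives biological replicates, and if an extract was shared the p-values describe those extracts.

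A set of 13 genes changed by at least 2-fold in opposite directions at the times: 12 fell at 2 h and rose at 5 h, including SAG29, LTP3, LTP4 and HSFA6A, and AT5G42530 did the reverse (1.18 and −1.12). Photosynthesis genes had medians of 0.0684 at 2 h and −0.351 at 5 h, with a median difference of −0.427 that passed the list test of the difference (adjusted p = 8.42e-05, and adjusted p = 0.198 with an estimated correlation). Cell wall genes had medians of 0.259 and −0.381, with a median difference of −0.469 that passed the same test (adjusted p = 0.00856, and adjusted p = 0.198 with an estimated correlation). Glucosinolate genes had medians of 0.338 and −0.607, with a median difference of −0.798 that passed it too (adjusted p = 3.68e-05, and adjusted p = 0.198 with an estimated correlation). Among 4224 kept probes without a gene name, which no comparison used, 328 were at least 2-fold higher and 67 lower at 2 h, and 405 higher and 179 lower at 5 h.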

How the results depend on the processing

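All alternatives were planned, and the batch alternative was not run because the 4 arrays share 1 slide. Counts stayed within 1.5 times their reported values and the correlation (0.8067) within its SD over single-array pairs (0.00112) in 256 cases and moved further in 24. With the Feature Extraction ratio, genes at least 2-fold lower numbered 1550 at 2 h, 3129 at 5 h, 1343 in 5 h against 2 h and 1098 at both times, and with the series matrix values 1210, 2696, 1432 and 878. A 2-fold size threshold, by its construction, left 1990 higher and 476 lower at 2 h, 2773 and 1487 at 5 h, 884 and 701 in 5 h against 2 h, and 1573 and 317 at both times. The correlation was 0.8189 with the Feature Extraction ratio, 0.8079 without background subtraction, 0.8046 with median centring, 0.8052 without a filter, 0.8055 with bright probes only, 0.8199 with the series matrix values and 0.8036 to 0.8058 with 1 array left out, where a lone array is assumed to vary like the others. With the replicate number as a block (replicate block), 8486 genes were higher and 8328 lower at 2 h, 9013 and 8974 at 5 h, and 6945 and 8083 in 5 h against 2 h. Across genes, which are not independent, the replicate differences at 2 h and 5 h correlated at 0.0591. That value is small, and it does not settle whether a shared replicate number pairs arrays. Between 42 and 49 of 75 list tests passed over the 16 alternatives, against 46, and under the 12 alternatives that can change a list test, single list results were the same in 886 cases, weaker in 8 and stronger in 6. The calls that ended stand beside their lists in the report. Abscisic acid synthesis and breakdown genes gained a call at 2 h with the Feature Extraction ratio (camera adjusted p = 0.0478, range 0.0478 to 0.174). Evening clock genes gained a call at 5 h without a filter (0.0386, range 0.0386 to 0.115). Reference genes gained a call at 5 h without a filter (0.0367, range 0.0367 to 0.176). At 2 h they gained a call with median centring (0.0427) or no filter (0.0305), in a range of 0.0305 to 0.0928. Without replicate 1 of 2 h, also counted as stronger, their median at 2 h was 0.282. Named genes were the same in 5828 cases, weaker in 126 (90 of them by the size threshold), stronger in 22 and reversed in 7. The reversed log2 changes were GI at 5 h with the Feature Extraction ratio (−0.105) and the series matrix (−0.013), ELF3 (−0.054) and UBC21 (−0.071) at 5 h with the Feature Extraction ratio, GAPC2 at 5 h (−0.081) and EF1A in 5 h against 2 h (−0.301) with the mean of probes, and EF1A with median centring (−0.34). For GI, ELF3 and UBC21 the reversal came with a lower median of all genes (−0.135 with the Feature Extraction ratio, −0.0442 with the series matrix), relative to which GI stood at 0.03 and 0.031, ELF3 at 0.081 and UBC21 at 0.064. Probes of GAPC2 and EF1A went opposite ways, and the cause of the EF1A reversal with median centring was not tested. Leaving out saturated probes removed none, and Aquantile leaves ratios as they are, so neither tests stability, and the size threshold and the intensity trend with a robust prior do not enter the list tests. Signal over background limits the seed list, of which 6, 3 and 7 of 13 members were dim on a side at 2 h, at 5 h and between them.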

Other observations

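The tests of gene families in this part were chosen only after the data were seen. Families of genes sharing a symbol stem with at least 10 members, 126 in number, were tested with camera in the 3 comparisons (378 tests, adjusted together), and 58 passed. Those described were picked from these by eye, after their values were seen, mostly because the fixed lists did not hold them. At 2 h U-box ubiquitin ligases (PUB) rose in 17 of 20 cases and fell in 2 (median log2 change 0.835, adjusted p = 0.000844, and adjusted p = 0.751 with an estimated correlation), with PUB19 at 4.71 and PUB18 at 4.43. The MAPKKK protein kinases rose in 11 of 13 cases and fell in 1 (median 1.43, adjusted p = 0.00312, and adjusted p = 0.751 with an estimated correlation), with MAPKKK18 at 5.04. The SAUR genes, many of them auxin-induced, fell in 11 of 14 cases and rose in 2 (median −1.33, adjusted p = 0.00926, and adjusted p = 0.751 with an estimated correlation), with SAUR22 at −2.58. At 5 h all 13 PTAC genes, which encode proteins of the plastid transcription machinery, fell (median −0.826, adjusted p = 0.00287, and adjusted p = 0.751 with an estimated correlation), with PTAC5 at −1.37.

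In 5 h against 2 h glycosyltransferases (UGT) were higher in 38 of 54 cases and lower in 13 (median 0.747, adjusted p = 0.000277), with UGT74E2 at 2.76. The CIPK kinases, which act with calcium sensors, were higher in 18 of 21 cases and lower in 2 (median 0.547, adjusted p = 0.000806), with CIPK16 at 1.53. Autophagy genes (ATG) were higher in 15 of 18 cases and lower in 1 (median 0.331, adjusted p = 0.00293), with ATG8H at 1.66. Fasciclin-like arabinogalactan proteins (FLA), found at the cell surface, were lower in 14 of 16 cases and higher in 1 (median −0.84, adjusted p = 0.00127), with FLA8 at −1.49. For each of these families the adjusted p = 0.751 with an estimated correlation.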
